A study of Caenorhabditis elegans with 2 samples.

How the data were processed

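The samples were 2 biological replicates of late embryos of strain OP305, immunoprecipitated for eGFP-tagged NHR-11, with a fragment size range of 150 to 350 per the labels. The deposited files were peak lists in the narrowPeak format on the ce11 and ce10 builds. Per the deposited file descriptions, each replicate list held peaks and background regions called from that replicate's alignments and a control, the pooled list was called from both replicates, and the thresholded list was derived from the pooled and replicate lists. The aligner, the peak caller, their versions and settings, and the IDR threshold were not given in the sources used here. The control named in the labels was not analysed here.

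The signal of each peak is the authors' deposited value, in the unit of their caller; it was used only to describe and rank peaks within a list and to compare the same sites between replicates. The deposited −log10 column gives the false discovery rate (q-value) of each peak within its own list, as read from its format and values, and was turned back into a rate. The thresholded list had rates of 0.0189 to 0.134. The replicate lists reached far into the background, with 25795 peaks in replicate 1 and 29222 in replicate 2, of which 152 and 47 had a rate of at most 0.05. The ce11 pooled list held 9931 peaks. Signal values of the replicates were not scaled to each other as far as the sources state, so a ratio between replicates also holds any difference in depth, which is unknown.

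All coordinates are on ce11 (WBcel235), counted from 1. Gene positions came from the Ensembl 115 annotation (46890 genes on the 6 chromosomes) and sequence from the RefSeq WBcel235 genome; no ce11 peak reached past a chromosome end. The ce10 lists were counted but never converted. Each summit was assigned to the nearest gene 5' end, and a gene was called bound where a thresholded summit lay within 1000 bp of its 5' end. A summit was placed in a coding exon, UTR, noncoding exon or intron in that order of preference, and otherwise called intergenic. Peaks were aligned to the genome with BLAST 2.17.0, and 11 of 101 thresholded peaks matched at least 1 other place at 90% identity or more over at least 50 bp. Matches that touched were merged and counted once, and matches overlapping the peak itself were not counted.

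Replicates were compared by overlap of at least 1 bp, with 1000 random placements of the replicate 1 peaks within their chromosomes. Peaks were matched between replicates in order of signal, and a Gaussian copula mixture (IDR) was fitted to the ranks of the 9134 pairs. Promoter-proximal shares were compared with 10000 random placements and with low-ranked summits. Gene lists (18, fixed in advance) and biotypes (11) were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, over a background of 32107 genes with any replicate summit within 1000 bp of the 5' end; 137 of these had a thresholded summit, 72 of them protein-coding. The list of the transgene's own genes had 1 member in that background and 0 bound. Neighbouring genes can be bound through the same summit, so genes are not independent, and the tests were repeated with sites as units. Motifs (7, fixed in advance) were counted on both strands within 50 bp of the summit and in flanks of the same size 500 bp away on both sides. GC content used 100000 sign flips. Limits for a count of 0 correspond to 3 counts. Intervals of shares and odds ratios were at the 95% level.

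The alternatives were the ce10 lists, other numbers of top peaks (500 and 2000), reciprocal overlap of at least 50% of both peaks, ranking by false discovery rate, IDR thresholds of 0.01 and 0.1, other starting values, windows of 500 and 2000 bp, the stronger part of the list, other backgrounds and controls, motif windows of 100 bp, and leaving out each replicate by taking the 101 strongest peaks of the other. Groups, tests, gene lists, motifs, the naming rule and these alternatives were fixed before the data were examined. Added after the data were seen were the false discovery rate limit, the sites without matches elsewhere, and sites within the top 2000 of both replicates. Other backgrounds were also added then (protein-coding genes for the lists, and all annotated genes or no piRNA genes for the biotypes). So were other expected shares for chromosome X, sites as units, overlapping peaks counted once, and the tests of chromosomes II, IV and V. The text names the nearest gene of the 25 strongest thresholded peaks, a second gene within 1000 bp, the 2 transgene genes, and up to 5 bound members per fixed list; any other name is marked as chosen after the values were seen.

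The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The IDR fit and the overlap, promoter, gene list and motif tests were tried on simulated data, and the other steps were not. The IDR fit, on 9134 simulated pairs with 20.0% reproducible, estimated 19.0%, recovered 83.4% of the reproducible pairs and made 4.76% false calls. The simulated reproducible pairs were more strongly correlated than the fit to the data estimated (0.598). This recovery therefore need not hold for the data. The overlap test found all 30 planted sites among 101, and 0% of 40 random lists passed. The promoter test passed for 2.5% of 40 random sets of 101 summits. The list test called a list in 3% of 100 random sets of 137 genes, and called a planted set of 7 ribosomal protein genes as the only list. The random genes were drawn singly, whereas bound genes in the data can share a summit, so the 3% need not hold for the data. A planted motif in 30 of 101 windows was the only motif called.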

Results

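Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for NHR-11, a member of the nuclear hormone receptor family of transcription factors, in the nematode Caenorhabditis elegans. The strain, OP305, carried a transgene encoding NHR-11 fused to the fluorescent protein eGFP, together with an unc-119 mutation. Whole embryos of mixed sex at a late stage formed a single group of 2 biological replicates. The labels named no second condition, so the comparisons were between the replicates, between bound sites and the rest of the genome, and between bound sites and their own flanks. The measurements were the authors' peak lists, with a signal value for each peak. No read counts were given, so the depth of each library was unknown. Intervals below cover counting error only, and the number of replicates was 2 throughout.

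The authors' list of reproducible (thresholded) peaks on the ce11 build held 101 peaks, and their list on ce10 held 137. The first question was which genes lay beside the ce11 peaks. Of the 101, 1 peak at str-33 overlapped a stronger one and the same replicate peaks, which left 100 separate sites. The strongest site lay in an intergenic repeat on chromosome I (933353 to 933667), 4974 bp upstream of the 5' end of nas-30, an astacin-type metalloprotease gene. Its signal of 447 was 2.84 times that of the second site. It ranked first in both replicates, with 232 in replicate 1 and 246 in replicate 2, and its sequence matched 45 other places in the genome. The second site, with a signal of 157, lay on chromosome II (10563506 to 10563659), intergenic and 182 bp upstream of cdc-48.1, which encodes an AAA-type ATPase of protein quality control. Replicates 1 and 2 gave it 86.2 and 73.5.

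Ribosomal protein, chaperone and histone genes lay beside several of the 25 strongest sites. A site at chromosome III 3867413 to 3867768 lay 263 bp upstream of the ribosomal protein gene rpl-3, with a signal of 125 (49.8 in replicate 1 and 74.7 in replicate 2). Sites with signals of 91.3 and 76.7 lay 443 bp upstream of rpl-35 (chromosome III, 7854513 to 7854868) and 142 bp upstream of rps-12 (chromosome III, 5678978 to 5679333). The site at chromosome IV 17278403 to 17278758, with a signal of 106, lay 378 bp from the 5' end of hsp-1, an HSP70-family chaperone gene, and 168 bp downstream of that of the noncoding RNA gene F26D10.23. The HSP70-family genes F44E5.5 and F44E5.4 shared a site with a signal of 77.8 on chromosome II (11759332 to 11759687). Core histone genes had sites with signals of 90.5, between his-68 and his-67 on chromosome I (9988825 to 9989180), and 87.1, 113 bp upstream of his-37 on chromosome V (9546814 to 9547169). The his-68 site shared stretches of up to 50 bp with 5 other places in the genome.

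Other strong sites lay just upstream of tasp-1, idhg-1 and atx-2. On chromosome III, these distances were 58 bp for tasp-1 (10759071 to 10759426, signal 97.8), 44 bp for idhg-1, an isocitrate dehydrogenase subunit gene (4568575 to 4568930, signal 93.3), and 48 bp for atx-2, the ataxin-2 gene (10461163 to 10461518, signal 82.6). K01G5.10, mlcd-1 and ecps-1 were the second genes within 1000 bp of these sites. A site on chromosome II (9757610 to 9757965, signal 92.1) lay 164 bp upstream of the noncoding RNA gene ZK1321.5 and 444 bp from the 5' end of the potassium channel gene shk-1. The site at chromosome X 11605746 to 11606101, with a signal of 130, fell in a noncoding exon of F52D10.7. Beside nspc-17 on chromosome X (14525704 to 14526059), a site with a signal of 127 lay 701 bp upstream of the 5' end. Of the other sites among the 25 strongest, those nearest to F55G7.5, F43C1.7, pot-3 and cest-16 lay 1416, 4644, 1291 and 3361 bp from a 5' end. A tRNA gene (WBGene00014538, signal 109) and the piRNA gene 21ur-12946 (signal 108) were nearest to sites on chromosome X (11094000 to 11094355, intergenic, and 2996984 to 2997339, intronic), at 1495 and 1320 bp. The noncoding RNA gene C30E1.9 lay 184 bp from a site on chromosome X (16929552 to 16929907, signal 86.5). Pseudogenes were nearest to sites on chromosome V (3098796 to 3099151, signal 84.1, WBGene00016861), which matched 23 other places in the genome, and on chromosome IV (11103498 to 11103853, signal 77.0, WBGene00011483), in a noncoding exon with srlf-17 as the second gene. The second genes of the rps-12 and his-37 sites were ska-3 and C50F4.6, and that of the F52D10.7 site was F52D10.12. All 25 ranked within the top 500 of both replicate lists.

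The 2 replicates shared their strongest sites far more often than chance placement gave. Of the 101 strongest peaks of replicate 1, 27 (26.7%) overlapped the 101 strongest of replicate 2, against a mean of 0.092 at random (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Among the top 500, 99 overlapped (19.8%), and among the top 2000, 337 (16.9%). Over 9134 matched peaks, Spearman's rho of the signal was 0.175 and Pearson's r of the log2 signal was 0.270, both across peaks, which are not independent replicates. Across the 100 thresholded peaks found in both replicates, rho was -0.0076, and with the overlapping pair counted once it was 0.0117; these peaks had been selected on the pooled signal, which lowers a correlation between its parts.

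The replicates differed less in signal over the 25 strongest sites than over the whole thresholded list, a difference that was not tested. The log2 ratio of replicate 1 to replicate 2 had an SD of 0.43 over the 25 strongest sites and of 0.71 over the thresholded peaks (0.70 with the overlapping pair counted once). The cdc-48.1 site had a ratio of 0.23 and the rpl-3 site one of -0.58. By contrast, the site 154 bp from cyp-13A2 ranked 23 in replicate 1 and 5882 in replicate 2. The thresholded list was identical to the 101 strongest peaks of the authors' pooled list; 12 of these ranked below the top 2000 of at least 1 replicate and 1 had no peak in replicate 2. A reproducibility model (irreproducible discovery rate, IDR) was refitted to the 2 replicate lists. It placed 19.9% of matched peaks in the reproducible part, with 157 peaks at an IDR of 0.05. The correlation estimated for that part was 0.598, on the Gaussian scale of the model and not between ranks. At 0.01 the refit gave 57 peaks and at 0.1 it gave 253. Of the thresholded peaks, 88 overlapped a replicate 1 peak that passed the refit at 0.05, and 30 had a pooled false discovery rate of at most 0.05.

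**Figure D1:**
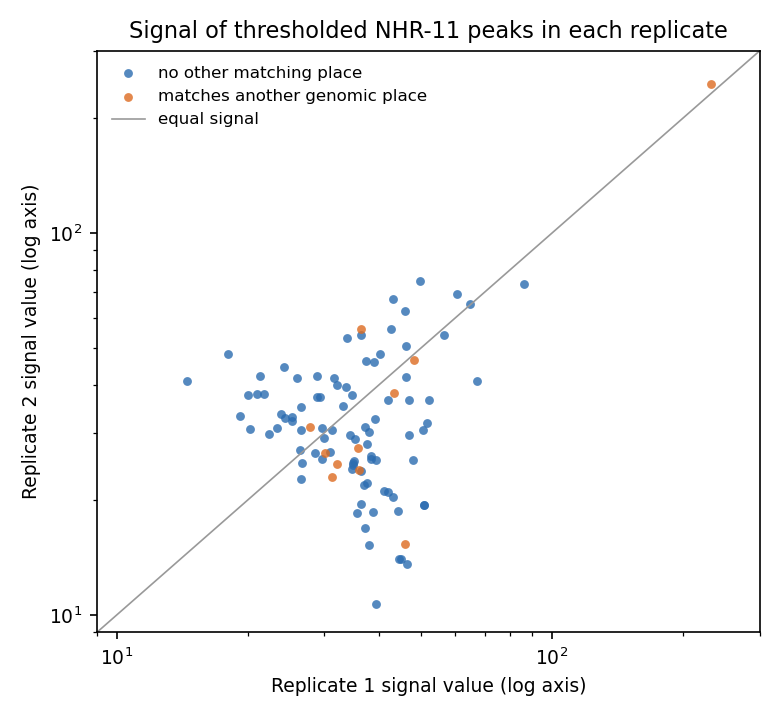
Signal of each thresholded peak in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), with 1 point per peak and a line at equal signal; orange points match another place in the genome. The strongest site stands apart at 232 and 246, and Spearman's rho was -0.0076 over the 100 peaks found in both (0.0117 with the overlapping pair counted once), which were selected on the pooled signal.

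Bound sites lay close to gene 5' ends more often than random positions did. Of the 101 summits, 67 (66.3%, 95% Wilson interval 56.7 to 74.8%) lay within 1000 bp of a gene 5' end, against 49.3% of random positions on the same chromosomes (one-sided permutation test, p = 0.0005). These 67 lay a median of 172 bp from the nearest 5' end, 43 of them upstream. For protein-coding genes alone the share was 48.5%, against 35.1% at random (p = 0.0032, one-sided permutation test). Summits in the lower-ranked part of the replicate lists were within 1000 bp of a 5' end in 52.8% of cases (14524 of 27509), a lower share than at thresholded sites (two-sided Fisher's exact test, odds ratio 1.76, p = 0.00685). By annotation, 56 summits were intergenic, 20 intronic, 9 in 3' UTRs, 8 in noncoding exons, 4 in 5' UTRs and 4 in coding exons. More than 1 gene lay within the window at 41 of the 67 summits, so the nearest gene was not the only choice there.

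**Figure D2:**
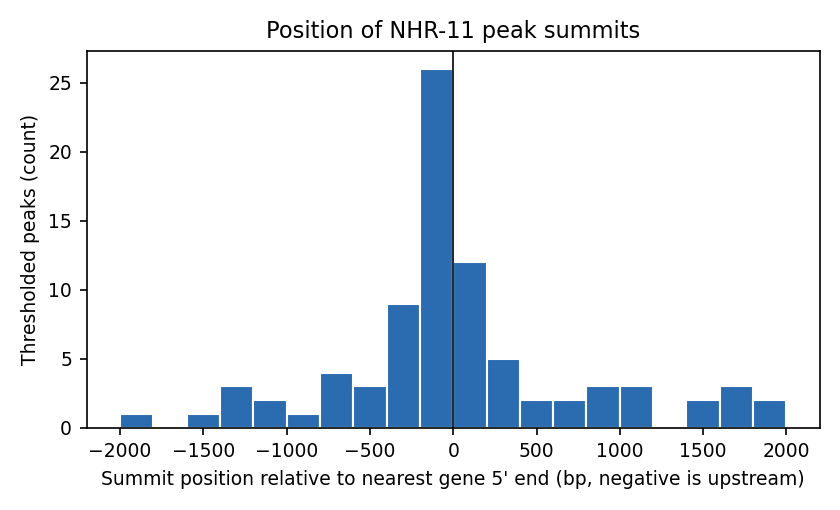
Number of thresholded peaks (vertical axis) by position of the summit relative to the nearest gene 5' end in bp (horizontal axis, negative values upstream), in bins of equal width, for summits within 2000 bp. Most of the summits lie close to the 5' end, and 43 of the 67 within 1000 bp are upstream.

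Ribosomal protein genes and histone genes were the fixed gene lists with more bound members than the background. Of 72 ribosomal protein genes with any replicate peak within 1000 bp, 7 (9.72%) had a thresholded summit there, against 0.406% of other genes (odds ratio 26.4, 95% interval 10.02 to 59.1; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 4.6e-07 over 18 lists). Besides rpl-3, rpl-35 and rps-12, the members were rpl-15 (signal 66.3), rps-28 (64.1), rpl-20 (63.2) and rps-19 (60.5), of which rpl-20 and rps-19 were the second gene beside a summit; the naming rule stopped at 5 members, and rpl-20 and rps-19 were named after their values were seen. Of 41 histone genes, 3 were bound, through 2 sites (his-68 with his-67, and his-37), with an odds ratio of 18.8 and an adjusted p of 0.00648. Counted by sites, the histone odds ratio was 24.1 with a larger adjusted p of 0.032 (Fisher's exact test). Without the 11 sites whose sequence matched another genomic place, 1 histone gene was left and the adjusted p was 0.525 (odds ratio 6.55; the highest over the alternatives was 35.0, at 500 bp). All 7 ribosomal protein genes remained then, with an adjusted p of 2.2e-07. With replicate 2 left out, 4 ribosomal protein genes were bound (adjusted p = 0.00156, Fisher's exact test). Counted by sites, the ribosomal protein odds ratio was 26.4 with an adjusted p of 4.1e-07 (Fisher's exact test).

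None of the other 16 lists passed the adjusted threshold. Chaperone genes had 2 bound members of 54, hsp-1 and hsp-110 (signal 70.3), which did not pass the adjusted threshold (odds ratio 9.09, adjusted p = 0.134, Fisher's exact test). The list, fixed by gene names, did not hold the HSP70-family genes F44E5.5 and F44E5.4, so their site is outside this count. The detoxification list had 2 of 168, the cytochrome P450 gene cyp-13A2 (56.5) and the glucuronosyltransferase gene ugt-60 (55.5), and the lipid metabolism list 1 of 98, the carnitine acyltransferase gene cpt-6 (59.9). The basic helix-loop-helix gene hlh-6 (59.5), active in pharyngeal glands, was the bound member of both the pharynx list (1 of 12) and the list of other transcription factors (1 of 164). Neuropeptide and chemoreceptor genes had 5 bound of 893, namely srlf-17 (77.0), str-33 (65.1), srd-10 (56.8), sre-1 (56.6) and nlp-63 (55.9), an odds ratio of 1.33 (adjusted p = 1, Fisher's exact test). No nuclear hormone receptor gene was bound (0 of 183, which allows a share of up to 1.64%), nor any collagen or cuticle gene (0 of 223, up to 1.35%). Mitochondrial genes (0 of 83, up to 3.61%) and splicing genes (0 of 52, up to 5.77%) had no bound member. These limits lie above the 0.43% of other genes that were bound, so the zeros do not show avoidance. Marker lists of epidermis (0 of 14), intestine (0 of 16), body wall muscle (0 of 17), neurons (0 of 17) and germline or early embryo (0 of 13) were too short to exclude shares below 21.4, 18.8, 17.6, 17.6 and 23.1%, in that order. Whole embryos were used, so no cell type was assigned.

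Genes for small nuclear and small nucleolar RNAs were also bound more often than other genes. Of 70 snRNA genes, 5 had a thresholded summit within 1000 bp (odds ratio 18.6, 95% interval 5.75 to 46.7; adjusted p = 4.7e-05 over 11 biotypes, two-sided Fisher's exact test). They lay at 4 sites; sls-2.2, beside the noncoding RNA gene C17C3.23 on chromosome II (5543652 to 5544007, signal 74.0), was within the naming rule, and sls-2.1, sls-2.3, sls-2.4 and R07E5.16 were named after their values were seen. Without the sites matching other places, 2 of the snRNA genes were left and the adjusted p was 0.0816. Over all alternatives the snRNA odds ratio ranged from 7.76 to 31.5. Without replicate 1 it was 9.92, with 3 genes (adjusted p = 0.0151, Fisher's exact test). Counted by sites it was 19.7, with a larger adjusted p of 0.00039 (Fisher's exact test). Of 263 snoRNA genes, 10 were bound, through 7 sites (odds ratio 9.87, 95% interval 4.57 to 19.04; adjusted p = 1.2e-06, Fisher's exact test). C06A1.9, a snoRNA gene 525 bp from the summit beside cdc-48.1, was among them. Over the alternatives this odds ratio ranged from 5.67 (500 bp) to 11.1 and stayed past the threshold. Without replicate 1 it was 6.19, with 7 genes (adjusted p = 0.00123, Fisher's exact test). Counted by sites it was 8.04, with a larger adjusted p of 0.00039 (Fisher's exact test). By Fisher's exact test, the share of bound piRNA genes was low (13 of 10799, odds ratio 0.206, adjusted p = 7.3e-10), but these genes lie in dense clusters, and counted by sites the odds ratio was 0.724 with an adjusted p of 0.946. Without replicate 1 the odds ratio by genes was 0.483, and without replicate 2 it was 0.0389. Protein-coding genes had an odds ratio of 1.53 (72 of 13487, adjusted p = 0.0409, Fisher's exact test), which fell below 1, to 0.802, without piRNA genes in the background. Without replicate 1 it was 1.13 (adjusted p = 0.615, Fisher's exact test). The call was also lost at 500 bp, in the stronger part of the list and with sites as units. There the adjusted p values were 0.146, 0.124 and 0.145 (Fisher's exact test). With all annotated genes as background it was lost too (adjusted p = 0.054), as for sites in the top 2000 of both replicates (0.083, Fisher's exact test). At 2000 bp and without replicate 2 the call was kept. It was also kept without sites matching elsewhere and with overlapping peaks counted once. For tRNA genes (4 of 467) the odds ratio of 2.05 did not pass (adjusted p = 0.308, Fisher's exact test).

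**Figure D3:**
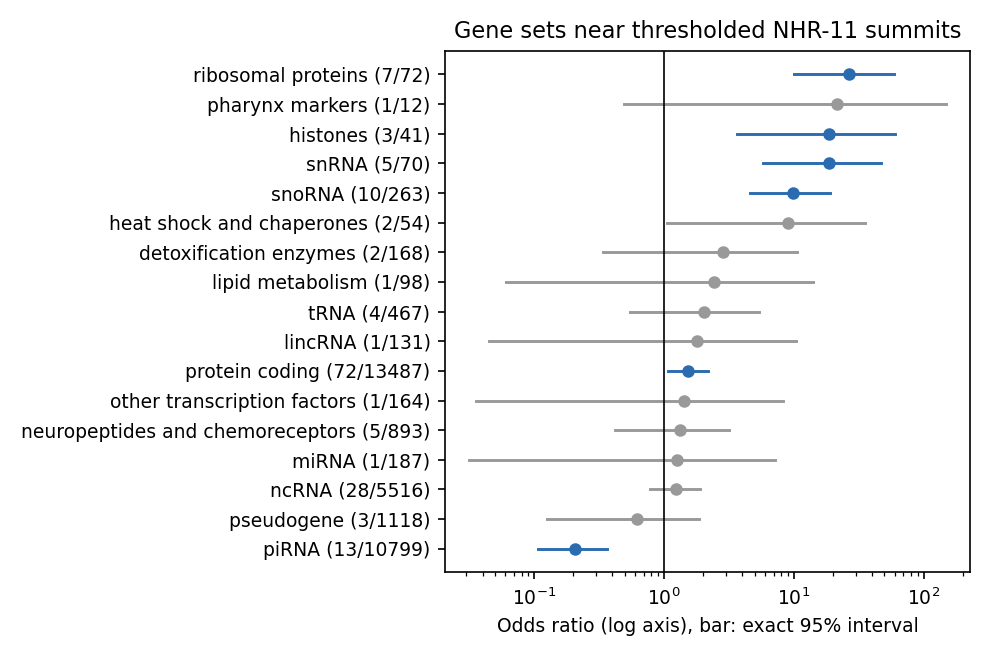
Odds ratios (horizontal log axis) with exact 95% intervals for each gene list or biotype with at least 1 bound gene, labelled with bound genes over genes in the background; blue marks an adjusted p below 0.05. Ribosomal protein genes have the highest odds ratio among those past the threshold (26.4), and piRNA genes the lowest (0.206).

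Thresholded peaks were spread over all 6 chromosomes. Chromosome X held 12 of the 101 (11.9%, exact 95% interval 6.29 to 19.8%), against 12.8% of gene 5' ends (two-sided exact binomial test, p = 0.882). Against its 17.7% of the genome, p was 0.151 (exact binomial test). The 101 strongest peaks of replicate 2 alone had 20.8% on X (p = 0.0244 against gene 5' ends, exact binomial test). Those of replicate 1 alone had 14.9% (p = 0.551 against gene 5' ends, exact binomial test). The shares of single replicates were not tested against the share of the genome. Chromosome II, singled out after the counts were seen, held 27 peaks (26.7%, exact interval 18.4 to 36.5%) and makes up 15.2% of the genome (adjusted p = 0.0191 over the chromosomes, exact binomial test). Against its share of protein-coding genes, 17.3%, the adjusted p was 0.0511. In the 101 strongest peaks of replicate 2 alone, 19.8% lay on chromosome II (p = 0.212, exact binomial test). The tests of chromosomes V and IV were not planned either. Chromosome V held 13 peaks (12.9%), below its 25% of protein-coding genes (adjusted p = 0.0230, exact binomial test) but not past the threshold against its 20.9% of the genome (adjusted p = 0.149). Chromosome IV held 16 peaks (15.8%), against 42.02% of all gene 5' ends (unadjusted p = 2.4e-08, exact binomial test), 16.4% of protein-coding genes and 17.5% of the genome (adjusted p = 1 and 0.793).

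The summits did not carry the hormone receptor half-site RGGTCA more often than their flanks. It was found within 50 bp of 2 of 101 summits and in 8 of 202 flanks (odds ratio 0.490, two-sided Fisher's exact test, adjusted p = 1 over 7 motifs). GAGAGA was found at 15 summits (14.9%) and in 12 flanks (5.94%), an odds ratio of 2.76 with p = 0.017 and an adjusted p of 0.119 in Fisher's exact test. Against low-ranked summits instead of flanks, GAGAGA passed the threshold (odds ratio 3.42, adjusted p = 0.00223), as it did in replicate 2 alone (3.08, adjusted p = 0.0153, Fisher's exact test). It did not pass in replicate 1 alone (2.53, adjusted p = 0.1625) or with windows of 100 bp (2.11, adjusted p = 0.148, Fisher's exact test). With overlapping peaks counted once it did not pass either (adjusted p = 0.119, Fisher's exact test). WGATAR (19 summits, 39 flanks), AGTGCA (3 and 6), CACGTG (1 and 1), TTTCGCGC (1 and 1) and TGACTCA (0 and 3) had adjusted p values of 1. Of 2080 sequences of 6 bases scanned, 0 passed the adjusted threshold by Fisher's exact test and 125 had an unadjusted p under 0.05. The GC content was 39.5% ± 11.1 (SD over 101 peaks) at summits and 35.9% ± 6.04 in flanks, a difference of 3.58 percentage points that was positive at 64 of 101 peaks (two-sided permutation test, p = 0.0026).

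The lists held fewer peaks around nhr-11 than an even spread over the genome gave. Around nhr-11 itself (chromosome IV, 9070003 to 9073622), the region extended by 20 kb on each side held 1 pooled peak, of rank 826 and signal 37.6 (9091232 to 9091587), where 4.32 were given by an even spread. The replicate lists each held 3 peaks there, against 11.2 and 12.7, and none lay within the gene. Around unc-119 (chromosome III, 10902641 to 10908935) the pooled list held 5 peaks against 4.59, and the replicate lists 12 each against 11.9 and 13.5. The strongest nearby peak stood at 8.32% of the pooled list for nhr-11, counted from the top, and at 4.52% and 35.6% of the lists of replicates 1 and 2. The corresponding positions for unc-119 were 19.7, 4.69 and 7.38%. The thresholded list held 0 peaks in both regions, where an even spread gave only 0.0439 and 0.0466, so these zeros were uninformative.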

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

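Some tests were chosen only after results were seen. These were the tests without sites matching elsewhere, on sites in the top 2000 of both replicates, and with sites as units. Overlapping peaks counted once, the false discovery rate limit, other expected shares for X, and the tests of chromosomes II, IV and V were others. Backgrounds of protein-coding genes for lists, and of all genes or no piRNA genes for biotypes, were chosen then too. Of the alternatives to the main results, 49 kept the call or stayed within 1.5 times the count, 13 moved and 4 turned in direction. The 13 include the nhr-11 and unc-119 positions without a replicate and the correlation over thresholded peaks, all counted as moved by rule. A count of lists or biotypes could stay within the limit although a member dropped out. For single lists, biotypes, motifs and chromosome II, 123 kept the call, 10 weakened, 2 strengthened and 11 turned. The promoter-proximal share stayed past its threshold under each alternative, between 48.5% (protein-coding genes) and 83.2% (2000 bp). Thresholded peaks numbered 137 on ce10, and 30 on ce11 at a false discovery rate of at most 0.05. The replicate correlation was -0.0076 over thresholded peaks alone. The IDR refit gave 57 peaks at 0.01 and 253 at 0.1, as a stricter or looser limit must. Leaving out each replicate in turn gave an X share of 14.9 to 20.8%; 0 to 1 motif past the threshold; and a position of the strongest nearby peak of 4.52 to 35.6% for nhr-11 and 4.69 to 7.38% for unc-119. With 16% in the stronger part of the list and 15.3% on ce10, the X share turned from below to above the share of genes in 4 alternatives, past the threshold only at 20.8%, without replicate 1. The motif count was 1 against low-ranked summits. The count of lists fell to 1 without sites matching elsewhere, and that of biotypes to 2 without piRNA genes and to 2 with sites as units. The protein-coding odds ratio became 0.802 without piRNA genes. The other odds ratios that turned passed no threshold in either setting: neuropeptides and chemoreceptors 0 (500 bp), 0.863 (stronger part) and 0.239 to 1.41 without a replicate; detoxification enzymes 0 (stronger part); tRNA 0.692 (500 bp) and 0 (stronger part); noncoding RNA 0.964 (2000 bp), 0.834 (no piRNA genes) and 0.953 to 1.45 without a replicate; and RGGTCA 0.214 to 1.76 without a replicate. Unless stated, the cause was not tested. The peak count, overlap, correlation and refit need both replicates, so no value without a replicate was possible. Unknown depth limits each statement on weak sites.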

Other observations

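Each test below was chosen after results were seen; for the draws of matched GC content the limits were set before drawing, but the 4 gene sets were combined because they had passed their tests. Genes for SL2 RNA, the spliced leader added to downstream genes of operons, were a bound group within the snRNA genes. Of 16 sls-2 genes with any replicate peak within 1000 bp (18 annotated), 4 had a thresholded summit there. The genes were sls-2.1 (signal 64.3), sls-2.4 (64.1), and sls-2.2 with sls-2.3, which shared a site with a signal of 74.0. Stretches of up to 60 bp at the shared site matched 2 other places, and without that site 2 genes were bound. The group was picked because its members were seen among the bound genes, so no test against chance is given.

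The strongest site lies in repeated sequence. Its sequence matched 45 other places in the genome, with stretches of up to 212 bp, and a continuous run of matches extended from 933353 to 934814 on chromosome I. Reads gathered from several copies may account for a signal 2.84 times that of the next site. Binding of NHR-11 to the repeat was not tested apart from this, because the reads and the control were not analysed here.

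Peaks near ribosomal protein, histone, snRNA and snoRNA genes formed a pattern, at 18 of the 67 promoter-proximal summits. In 1000 draws of replicate summits with matched GC content, the mean was 2.23 and the highest count 7. No draw reached the 18 seen. The 4 sets had been chosen because they passed against genes near summits of the same lists, so an excess was partly built in. The draws therefore do not exclude GC content as a cause. Without sites matching elsewhere, 2 of the 4 sets were still past the threshold, so repeated sequence stays open for the pattern as a whole. All 7 ribosomal protein genes and all 10 snoRNA genes were left, with a larger adjusted p of 4.2e-07 (Fisher's exact test). Matches of the kind counted here thus do not account for those genes. Shorter or less similar copies were not counted, so they stay open. Of the histone and snRNA genes, 3 of 8 were left, so repeated sequence stays open there. The sets were divided in this way after the outcome was seen. The snoRNA genes were not bound only through ribosomal protein genes, since 6 were bound through the 94 other peaks (p = 0.00050, two-sided Fisher's exact test), and RGGTCA half-sites were found at 0% of the 18 summits (exact upper limit 18.5%) and 8.33% of their flanks. A candidate explanation left open is that strongly transcribed genes are recovered in the immunoprecipitation without binding of NHR-11, and a biological one is recruitment of NHR-11 there; untagged controls and other factors were not analysed here, so these cannot be told apart.

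Few peaks lay around nhr-11. Of protein-coding genes, 0.611% had as few peaks within 20 kb in the pooled and both replicate lists (1, 3 and 3, against medians of 4, 11 and 12). For unc-119, also carried on the transgene, the share was 42.1%. The comparison was made because the counts had been seen to be low, so it describes how rare they are among genes and excludes no explanation. Whether a higher copy number of the region in the strain raised the control was not tested, since the control was not analysed here, and whether the control came from the same strain was unknown.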
